A study of Homo sapiens with 10 samples.

How the data were processed

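Total RNA from ST486 cells was purified with TRIZOL and a column clean-up, labelled with biotin and hybridised to 1-colour Affymetrix HG-U95Av2 arrays, per the labels. The deposited log2 expression values cover 12625 probe sets on 10 arrays, with a single value for each. GCRMA and affy are named in the submitters' processing notes, with no version; GCRMA corrects the background from probe sequence, normalizes across arrays and summarises the probes of a probe set on the log2 scale. The log2 scale is read from the values and from that tool, since the table states none. The authors' normalization was kept. GCRMA pulls dim probe sets towards a common floor, which shrinks the differences of weakly expressed genes. Scanner files were not analysed here.

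Arrays were grouped as STK38 shRNA or non-target shRNA from the labels, with the replicate number of the titles. The labels name 1 STK38 shRNA, so an effect of that hairpin on other transcripts cannot be separated from an effect of STK38 here. Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers to the RefSeq gene table of assembly GRCh38.p14, used only for names. Of 12558 probe sets left after removal of 67 Affymetrix control probe sets, 10943 had 1 gene, of which 10934 had a current symbol, 545 had several genes and 1070 had none. Genes were named only from probe sets with 1 gene; 253 of the changed probe sets had no single gene.

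Probe sets with a mean over all arrays under the 40th percentile (1.93) were left out, which left 7535. The groups were compared per probe set in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with trend, no covariate, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05; adjusted p-values of genes are from that fit. Plots were drawn with matplotlib 3.10.9. A fold is the ratio on the linear scale of a log2 difference. The background of each array was set at the 90th percentile of 23 control probe sets (2.36 to 2.66), a choice made after the values were seen. These were mouse, yeast and all reverse-strand controls, among them the reverse-strand probe sets of human ACTB and GAPDH. The brightest were one of ACTB (mean 4.47) and one of GAPDH (3.21). The background may thus be set high and counts of arrays above it low, and a level without them was not run. A gene not above the background on any array of a group is given a bound, "at least N-fold", from the other group's mean against the higher of background and signal on each array.

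Gene lists were compiled by hand from general knowledge, and the 34 lists, the tests, the filter, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured genes, 31 of them, were tested with camera in limma at a preset correlation of 0.01 between genes, on 1 probe set per gene (the highest mean over all arrays), two-sided, adjusted over the lists. With an estimated correlation 6 calls held. The unfolded protein and ATF4 response had a camera adjusted p of 0.00991, and autophagy and lysosome 0.0232. DNA replication, nucleotide synthesis, plasma cell and germinal centre each had 0.0491, just under the threshold. Leaving out arrays was not run with this setting. The fry test, which asks whether genes of a list move one way on balance without comparing them with other genes, called 21. Lists overlap: SHMT2, for example, belongs to the MYC-activated, nucleotide and ATF4 lists.

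The rule named STK38, STK38L, MYC, MAX, MXD and MXI1 family members and MOB1 genes whatever their values; the 12 largest rises and 12 largest falls among called genes whose groups did not overlap; up to 4 members per described list, called members and larger changes first; and up to 2 called members of each list of another cell type. The result of 1 gene among the largest falls is not reported here. MNT was counted with the MXD family, and MYCN and MYCL were added. Genes named for lists with no call and in the closing section, and ADAR, IFI16, TRBC1 and CIITA, were chosen after their values were seen.

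Data were simulated with the means and spreads of the 7535 probe sets of this comparison, with 200 changed in each of 20 simulations. There limma recovered 16.9% of changes of 0.3 on the log2 scale, 58.6% of 0.5, 95.3% of 1 and 100% of 2, and 5.25% of its calls were false. Far more probe sets, 2256, were called in the data. The adjustment depends on that share, so the recovery of small changes need not hold there. A list shifted by -0.3 was found in 20 of 20 simulations with 0 false calls in 440 tests of unshifted lists; genes were simulated as independent, so this says nothing of correlated genes. Alternatives covered scaling of the arrays, array weights, the filter, the variance model, the threshold, the choice of probe set, the set test, a replicate block and leaving out each array.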

Results

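Gene expression was measured in ST486, a human Burkitt's lymphoma cell line, 60 h after lentiviral transduction with a short hairpin RNA (shRNA) against STK38 or with a non-target control shRNA. STK38, also called NDR1, is a serine/threonine kinase of the NDR/LATS family, and the series title poses the question of how STK38 bears on the transcriptional activity of MYC, the oncogenic transcription factor that is translocated in Burkitt's lymphoma. Each group held 5 arrays, so the series held 10 arrays and allowed 1 comparison. The array was the Affymetrix HG-U95Av2, and its deposited log2 values ran from 0.35 to 12.65 with array medians of 2.12 to 2.25. The number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

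STK38 mRNA was lower in every array with the STK38 shRNA than in every control array. Its brightest probe set fell from 5.02 ± 0.22 in the controls to 2.83 ± 0.21 in the STK38 shRNA arrays (log2, SD, n = 5 each), which is 4.56-fold (log2 fold change -2.19, SE 0.14, limma adjusted p = 5.65e-08). The other STK38 probe sets fell by 1.16 and 0.82 on the log2 scale, and all 3 gave the smallest p that the two-sided exact permutation test allows with 5 against 5 arrays, 0.00794. The signal of the brightest probe set stood above the array background on 4 of the 5 STK38 shRNA arrays, that of the one with the smallest fall on 2 and that of the third on all 5. MYC mRNA fell as well. Its 4 probe sets had log2 fold changes between -1.64 and -1.38, and the brightest went from 8.68 ± 0.25 to 7.30 ± 0.34 (SD, n = 5 each), or 2.61-fold lower, with an adjusted p of 9.56e-06. No array of one group overlapped the other group at any MYC probe set, and the dimmest was above background on 4 of the 5 STK38 shRNA arrays.

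Genes of proteins that act with MYC or STK38 differed little. MXI1, a MYC antagonist that binds MAX, fell by 0.24 on the log2 scale (SE 0.082, adjusted p = 0.0371) at its brightest probe set, a call that was lost when most single arrays were left out, and by 0.26 (adjusted p = 0.0415) and 0.40 (adjusted p = 0.0210) at the others. MAX, the obligate partner of MYC, had a log2 fold change of 0.19 at its brightest probe set (SE 0.083, adjusted p = 0.108) and of 0.33 and 0.27 at the others that were tested, MNT of 0.43 (SE 0.17, adjusted p = 0.0680) and MOB1A, a co-activator of NDR kinases, of 0.30 (SE 0.12, adjusted p = 0.0878), none past the threshold. MXD1, MYCN and MYCL did not exceed background on any array. STK38L, the closest relative of STK38, was called lower (adjusted p = 0.00417). Its signal was above background on 4 control arrays and on 0 STK38 shRNA arrays, so the fall is given as at least 1.09-fold.

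**Figure D1:**
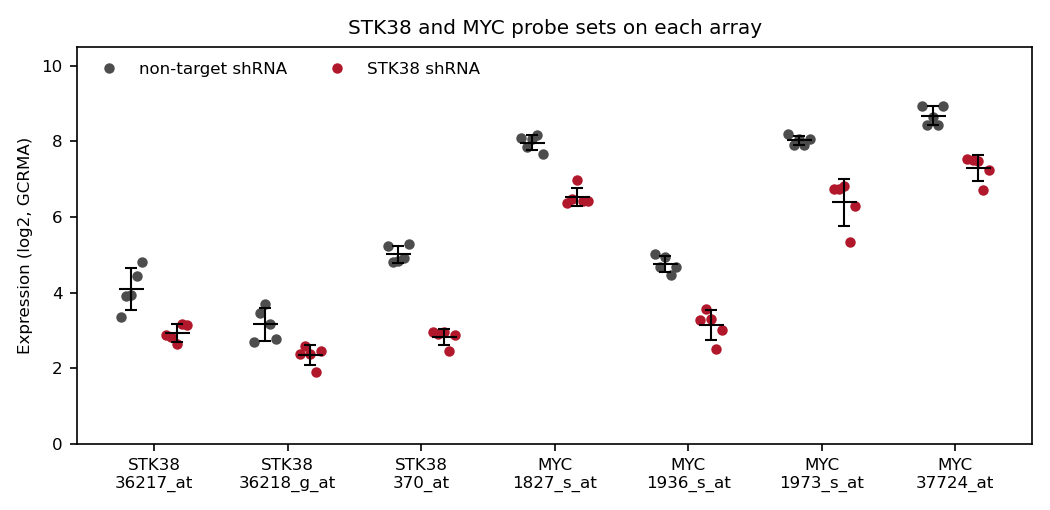
Expression (log2) of each STK38 and MYC probe set on the 5 non-target shRNA arrays (grey) and the 5 STK38 shRNA arrays (red). Each point is 1 array, and the bars give the mean and SD; at every probe set the STK38 shRNA arrays lay below the control arrays, for the brightest STK38 probe set at 2.83 ± 0.21 against 5.02 ± 0.22.

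Across the genome, NUCB2 and RAG2 were among the genes with the largest falls. NUCB2, a calcium-binding protein, fell 8.54-fold (log2 fold change -3.09, SE 0.18, adjusted p = 2.17e-08). RAG2, part of the V(D)J recombinase, fell 7.69-fold at one probe set, above background on 4 of the 5 STK38 shRNA arrays, and by 1.59 on the log2 scale at another. The ribosomal protein gene RPS12 fell 4.93-fold and had the smallest p of all probe sets tested (log2 fold change -2.30, SE 0.045, adjusted p = 4.98e-14). SHMT2, the mitochondrial serine hydroxymethyltransferase, fell 4.84-fold. TNFAIP8, YBX3, ME2 and CENPF fell by 2.15 to 2.21 on the log2 scale, with TNFAIP8 and CENPF above background on 4 of the 5 STK38 shRNA arrays. SUCLG2 fell as well (adjusted p = 6.46e-07), but was above background on 2 of the 5 STK38 shRNA arrays, with a mean of 2.29 there, so its measured difference of 2.01 is uncertain. WT1 was not above background on any STK38 shRNA array and was at least 2.75-fold lower there (adjusted p = 5.58e-07).

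The largest measured rises were smaller than the largest falls. LZTS3 rose from 2.44 to 4.96 (log2 fold change 2.52, SE 0.18, adjusted p = 1.32e-07); it was above background on 2 of the 5 control arrays, so the size of this rise and its place as the largest are uncertain. TULP3 rose 4.33-fold, with its 3 probe sets between 0.60 and 2.18 on the log2 scale. The lysosomal sialidase NEU1 rose 4.10-fold and PSAP, the precursor of the saposins, 3.33-fold. The sterol synthesis genes MVD, DHCR7 and ERG28 rose 3.52-fold, 3.21-fold and 3.20-fold. The histone genes H2AC6 and H2BC5 rose 3.87-fold and 3.69-fold, the phosphatase gene PTPN22 3.46-fold and TWF1, an actin-binding protein, 3.07-fold. The glucose transporter gene SLC2A3 was not above background on any control array and was at least 1.62-fold higher with the STK38 shRNA (adjusted p = 3.20e-05). In all, 2256 of the 7535 probe sets tested, or 29.9%, differed between the groups in limma, 1064 higher and 1192 lower with the STK38 shRNA. They covered 1742 of 5403 genes, of which 850 rose and 892 fell. Of the changed probe sets, 100 rose and 219 fell by at least 2-fold. The groups did not overlap at 22.1% of the probe sets tested, where chance gives 0.794%.

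**Figure D2:**
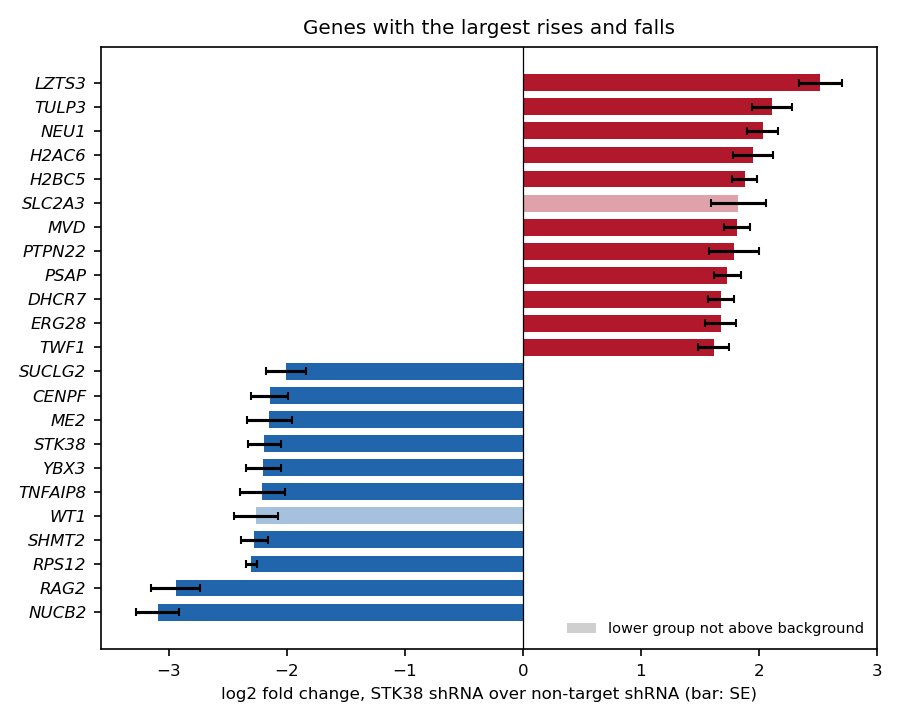
Log2 fold change (STK38 shRNA over non-target shRNA, n = 5 arrays each) of genes with the largest rises and falls; bars are drawn from 0 and error bars give the SE. Falls reached -3.09 (NUCB2) and rises 2.52 (LZTS3); the pale bars of WT1 and SLC2A3 show measured values for genes whose lower group was not above background.

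DNA replication genes fell together. Of the 48 genes measured, 36 fell and 0 rose (39 and 1 adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 9.30e-13). MCM6, a subunit of the replicative helicase, fell 3.71-fold (log2 fold change -1.89, SE 0.11), PRIM1, the primase subunit, 2.51-fold, and MCM4 2.50-fold. CDC6, which loads the helicase, fell by 1.87 on the log2 scale at its brighter probe set (above background on 4 of the 5 STK38 shRNA arrays), and its other probe set had -0.30. The mitosis list was mixed. Of its 44 genes, 14 fell and 5 rose (18 and 5 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.0129; adjusted p = 0.425 with an estimated correlation). CENPF, a kinetochore protein, fell 4.43-fold, TOP2A 2.20-fold, BUB3 1.75-fold and AURKA 1.64-fold.

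MYC-activated genes, a list fixed in advance from general knowledge, included 20 that fell and 3 that rose among 52 measured (21 and 3 adjusted over the list alone). The median log2 fold change was -0.17 (camera adjusted p = 9.95e-05), and the list was not called with an estimated correlation, adjusted p = 0.164. SHMT2 fell by 2.28 on the log2 scale (SE 0.11), PPAT, the first enzyme of purine synthesis, by 1.39 (SE 0.16), MCM4 by 1.32 (SE 0.18) and MCM5 by 1.28 (SE 0.24). Of 15 MYC-repressed genes, 3 rose and 1 fell, the same counts as adjusted over the list alone, and the median was 0.082 (camera adjusted p = 0.271). With single arrays left out this median ran from 0.027 to 0.11. TXNIP rose 1.46-fold, KLF6 1.35-fold and PTPN6 at least 1.19-fold, while GADD45A, above background on 4 of the 5 STK38 shRNA arrays, fell 1.63-fold.

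Nucleotide synthesis and ribosome biogenesis genes fell. In the nucleotide list 11 of 24 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 7.12e-05). Besides SHMT2 and PPAT, DUT fell 2.17-fold and TYMS, thymidylate synthase, 1.97-fold. Of 31 ribosome biogenesis genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.000200; adjusted p = 0.104 with an estimated correlation). RRP1B fell by 1.00 on the log2 scale, RRS1 by 0.73, UBTF, a factor for RNA polymerase I, by 0.70 and TSR1 by 0.62. Cytosolic ribosomal protein genes moved slightly the other way, with 19 higher and 6 lower of 46 (22 and 6 adjusted over the list alone) and a median of 0.11 (camera adjusted p = 0.00733; adjusted p = 0.143 with an estimated correlation). RPS19 rose 1.23-fold, while RPL10A fell 1.46-fold, RPL12 1.23-fold and RPS12 4.93-fold. Without STK38 shRNA replicate 4 this list was not called, adjusted p = 0.0700, nor was it with each array centred on its median (adjusted p = 0.0804) or by fry (adjusted p = 0.0739).

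Genes of the B cell lineage changed in both directions. Of 34 genes of B cell identity and receptor signalling, 15 fell and 6 rose, the same as adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.00733, and 0.384 with an estimated correlation). Over the alternatives this median ran from -0.28 to -0.13. The immunoglobulin gene IGHD fell 3.94-fold, TNFRSF17, the receptor BCMA, 3.79-fold, CD38 2.81-fold and TCL1A 2.18-fold. In the germinal centre list 10 of 17 genes fell and 1 rose, also when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.00260). MME, which encodes the surface peptidase CD10, fell 3.02-fold, FOXO1 1.74-fold and BCL6, the germinal centre repressor, 1.51-fold, with BCL6 above background on 3 of the 5 STK38 shRNA arrays. In the plasma cell list 7 of 18 genes fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 9.08e-05). IRF4 fell by 1.66 on the log2 scale at its brighter probe set and by 0.74 at the other, and XBP1 by 0.94 and 1.19.

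Genes of the unfolded protein and ATF4 response fell, 17 of 28 with 1 rise (18 and 1 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 2.67e-08). Besides SHMT2, SLC7A5 fell 2.32-fold and SLC3A2 2.03-fold; their products form an amino acid transporter. The transcription factor gene CEBPB fell 2.24-fold (log2 fold change -1.16, SE 0.15).

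Lysosomal and sterol genes rose. In the autophagy and lysosome list 18 of 27 genes rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 3.47e-09). Besides NEU1 and PSAP, the protease gene CTSA rose 2.37-fold (log2 fold change 1.25, SE 0.12), and MAP1LC3B, a marker of autophagosomes, rose by 1.07 at its brighter probe set and had 0.25 at the other. Of 21 cholesterol synthesis genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 6.59e-09; adjusted p = 0.0654 with an estimated correlation). TM7SF2 rose 2.98-fold and SC5D 2.76-fold, both enzymes of sterol synthesis like MVD and DHCR7.

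Some interferon response and MHC class I genes rose. In the interferon list 14 of 33 genes rose and 2, ADAR and IFI16, fell (17 and 3 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000577; adjusted p = 0.0684 with an estimated correlation). ISG15 rose 2.18-fold and IRF9, above background on 4 of the 5 control arrays, 1.83-fold, and OAS1 and GBP1, not above background on any control array, were at least 1.76-fold and 1.58-fold higher. Of 10 MHC class I genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00565; adjusted p = 0.111 with an estimated correlation). HLA-E rose 2.21-fold, TAPBP 1.54-fold, HLA-G 1.40-fold and HLA-F 1.38-fold.

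Of 50 oxidative phosphorylation genes, 19 rose and 3 fell (22 and 6 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00116; adjusted p = 0.0666 with an estimated correlation). The complex I subunits NDUFA6 and NDUFS5 rose 1.88-fold and 1.69-fold, COX7C rose 1.55-fold, and the ATP synthase subunit ATP5F1C fell 1.45-fold. Of 13 histone genes, 4 rose and 0 fell, also when adjusted over the list alone, with a median of 0.10 and a mean of 0.49 (camera adjusted p = 0.0121, and 0.0666 with an estimated correlation). Over the alternatives this median ran from 0.077 to 0.24. H2AC8 rose 2.71-fold, and H2BC21, not above background on any control array, was at least 1.23-fold higher. Probe sets of histone, HLA, immunoglobulin and ribosomal protein genes can bind transcripts of close relatives, so single members of these families are uncertain.

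**Figure D3:**
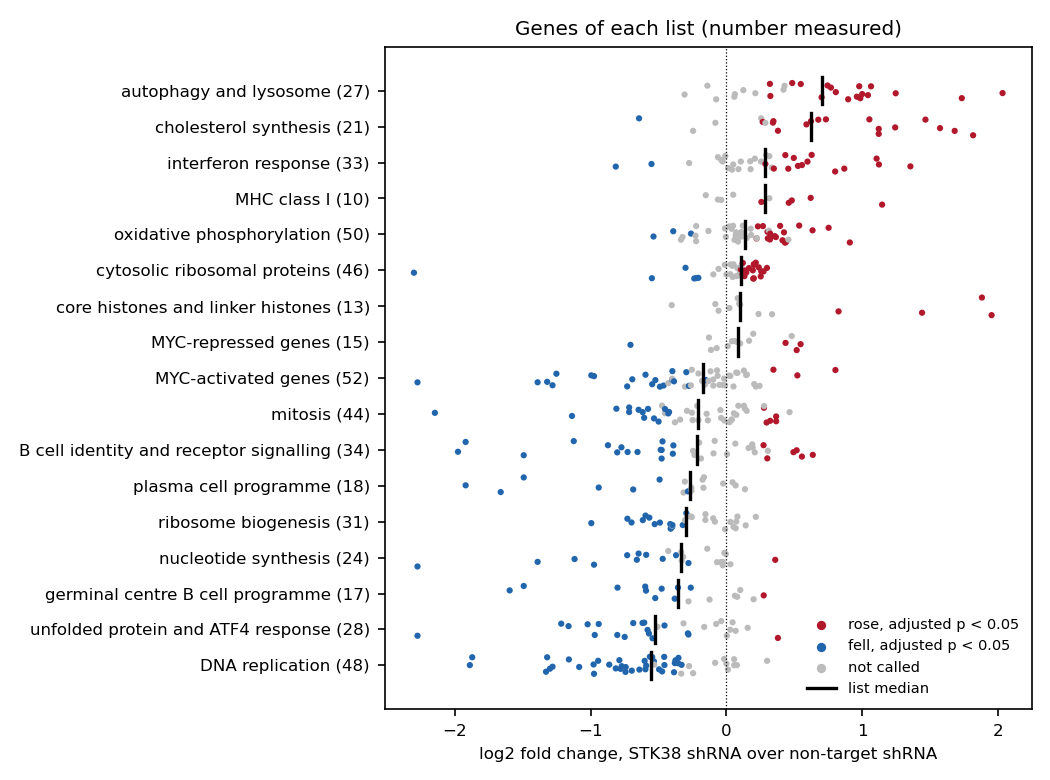
Log2 fold change (STK38 shRNA over non-target shRNA) of every measured gene in the 16 called lists and the MYC-repressed list, 1 point per gene. Red and blue points passed adjusted p of 0.05 as higher or lower, grey points did not, and black lines mark list medians, from -0.56 for DNA replication to 0.70 for autophagy and lysosome.

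The other lists were not called by camera. In the translation factor list 5 genes rose and 8 fell of 32 (adjusted p = 0.141), among immediate early genes 3 rose and 1 fell of 13 (adjusted p = 0.167), among heat shock proteins 4 rose and 6 fell of 22 (adjusted p = 0.356), and in the mitochondrial ribosome 2 rose and 3 fell of 14 (adjusted p = 0.410). In the proteasome 8 genes rose and 5 fell of 31 (adjusted p = 0.436), in glycolysis 4 rose and 5 fell of 17 (adjusted p = 0.436), and among apoptosis regulators 5 rose and 4 fell of 23 (adjusted p = 0.448). Of NF-kappaB targets 3 rose and 2 fell of 21 (adjusted p = 0.726), and of p53 targets 1 rose and 3 fell of 13 (adjusted p = 0.921). Of the 9 NDR-LATS pathway genes measured, STK38L was the 1 that fell (adjusted p = 0.410), and of 11 MHC class II genes CIITA was called lower, with 0 STK38 shRNA arrays and 1 control array above background (adjusted p = 0.526 for the list). No other member of either list passed the test. Adjusted over the list alone, these counts became 9 and 6 for the proteasome, 2 and 3 for p53 targets and 0 and 0 for MHC class II, and the others stayed as given. The test direction for p53 targets was down beside a median of 0.050, and the NF-kappaB median of 0.035 stood beside a mean of -0.0011. The YAP target list, with 4 measured genes and 0 called by limma (0 at an unadjusted p under 0.05), was too short for the set test.

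Markers of other cell types were not called higher in limma. Of 5 monocyte, 7 epithelial and 3 erythroid markers measured, 0 were called, and 0 had an unadjusted p under 0.05; camera gave an adjusted p of 0.895 for the monocyte list and 0.464 for the epithelial list. On STK38 shRNA replicate 4 alone the list means lay 0.43 (monocyte) and 0.39 (epithelial) above the control mean on the log2 scale, where the other STK38 shRNA arrays lay at -0.12 to 0.036 and -0.032 to 0.093. The fibroblast and endothelial list mean was at 0.092 on that array and at -0.38 to -0.20 on the other STK38 shRNA arrays. Of 4 T cell markers, 0 rose and 3 were called lower. LCK, above background on 4 of the 5 STK38 shRNA arrays, fell 2.33-fold (log2 fold change -1.22, SE 0.21), and TRBC1 fell by 0.52 on the log2 scale. CD247 was above background on 0 STK38 shRNA arrays and 1 control array, so no size is given. Of 6 fibroblast and endothelial markers 1 fell, VIM, which blood cells also express, by 2.80-fold; the list had a median of 0.0029 and a mean of -0.21 (camera adjusted p = 0.410). The counts of these lists were the same adjusted over the list alone. RNA quality signs did not differ between the groups: the 3' minus 5' difference was 0.93 ± 0.093 against 0.93 ± 0.096 for ACTB (two-sided exact permutation p = 0.976) and 0.29 ± 0.071 against 0.27 ± 0.081 for GAPDH (exact permutation p = 0.659, SD, n = 5 each).

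STK38 shRNA replicate 4 stood apart from the other arrays of its group, with a mean correlation of 0.982 with them where these 4 correlated with each other at 0.995 to 0.997, and a 75th percentile of 3.53 where the others lay at or above 3.93. Without this array 2817 probe sets differed, 1548 higher and 1269 lower, so that most rose where most fell with all arrays, and 2206 of the 2256 were called again in the same direction. The list calls need caution: 16 of 31 lists were called with the preset correlation and 6 with an estimated one. Of 100 splits of the arrays into 5 and 5, the real one included, 6 called 16 or more. The other 5 of these each kept 4 of the 5 arrays of a group together. They thus kept much of the real difference and cannot decide whether chance gives such a count.

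**Figure D4:**
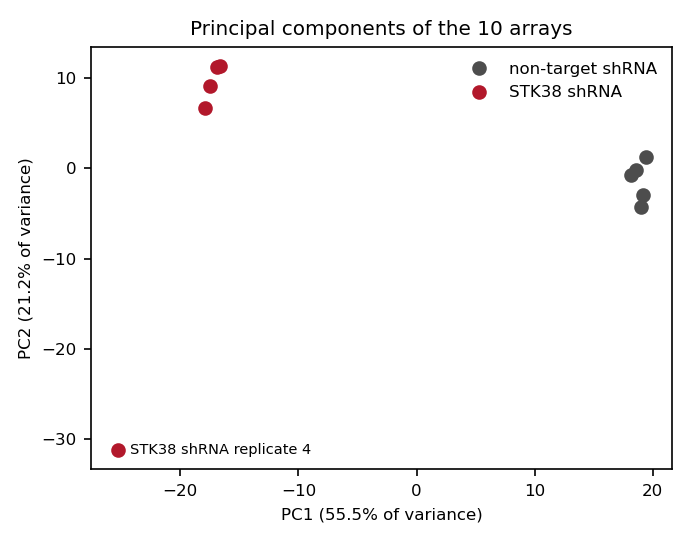
First and second principal components of the 10 arrays over the probe sets tested, with the percent of variance on each axis; grey points are non-target shRNA arrays and red points STK38 shRNA arrays. The first component (55.5% of the variance) separated the groups and the second (21.2%) set STK38 shRNA replicate 4 apart.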

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

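The tests of a wrong label and of degraded RNA below, and the count of lists with an estimated correlation, were chosen after the results were seen. Values were flagged where 1 array lay far from the other 4 of its group, measured as its gap to the nearest array divided by the range of the group. Of 260 such groups tested, 24 were flagged where chance gives about 13, and 17 of the 24 were STK38 shRNA replicate 4.

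STK38 shRNA replicate 4 was the low array for TNFRSF17 (gap ratio 0.916, at 3.21 against 4.63 for the next array), the brightest STK38 probe set (0.858), RAG2 (0.848), UBTF (0.814), BUB3 (0.798), EPRS1 (0.758), GADD45A (0.749), TOP2A (0.749), H2AC6 (0.732), PTPN6 (0.730), the dimmest MXI1 probe set (0.728), the second-brightest MAX probe set (0.719) and CEBPB (0.711). It also had the lowest 75th percentile (0.823), and it was the high array for SARS1 (0.846), the array median (0.749) and the background level (0.729). Elsewhere, STK38 shRNA replicate 3 was high for the second-brightest MYC probe set (0.832, at 6.97 against 6.48) and low for the ACTB 3' minus 5' difference (0.721), and STK38 shRNA replicate 2 was high for LZTS3 (0.741). Non-target shRNA replicate 1 was low for MOB1A (0.804), PTPN22 (0.739) and HK2 (0.737), and non-target shRNA replicate 4 was low for RPS19 (0.757).

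A wrong label for STK38 shRNA replicate 4 is argued against by its STK38 level, which was near its own group and far from the controls (measured at -0.217 of the distance from the other arrays of its group to the control mean). The signal on this array was not above its background, so the exact fraction is uncertain. Degraded RNA is argued against by its 3' minus 5' difference over ACTB and GAPDH of 0.67, within the range of the other arrays, which reached 0.70. The genes that rose deviated from the other STK38 shRNA arrays by a median of -0.30 (SE 0.016), opposite in sign to a stronger response. A drop across the whole array could give that sign too. Against uncalled genes of the same level they were lower at levels under 6, and slightly higher above (-0.079 against -0.108 at 6 to 9). A stronger response of the genes that rose therefore stays open. A dimmer array may account for part of the pattern: genes with mean levels between 3 and 6 that rose in the other 4 arrays deviated by a median of -0.50 (SE 0.016), and those at 9 and over by -0.0010. At levels of 3 to 6 the other arrays, each left out in turn, deviated by 0.018 to 0.090. Their reference mean includes replicate 4, which lowers it, and their gene sets were smaller (326 to 346 against 691), so the contrast is partly made by replicate 4. At levels under 3 the genes that rose deviated by -0.39, but uncalled genes by 0.074 (SE 0.0092) and genes that fell by 0.023, so weakly expressed genes as a whole were not lower. Genes that fell deviated by -0.44 and uncalled genes by -0.36 at levels of 3 to 6, so a stronger response among genes that fell stays open. The array was not dim throughout, since its median of 2.25 was the highest of all arrays. What lowered its values at levels of 3 to 6 stays open. Means of monocyte and epithelial markers were higher on this array than on the others, and means of fibroblast and endothelial markers higher than on the other STK38 shRNA arrays, by a cause that was not tested, so RNA of other cells in it stays open too.

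For the probe set count, 1 of 100 splits of the 10 arrays, the real one with 2256, gave as many. The highest of the others gave 0, but all of them mixed the groups. Mixing adds any real difference to the spread within each part. The real split thus ranked first, but that 0 does not measure how many calls chance gives. Nor can splits tell an effect of the hairpin from a difference between cultures, if each group came from 1. Chance splits were not excluded for the count of lists with the preset correlation either. There 6 of 100 splits, the real one included, called at least 16 lists and the highest other called 17. The 5 other splits each kept 4 of the 5 arrays of a group together. They thus kept much of the real difference and cannot decide whether chance gives such a count. Splits that kept 3 together called at most 8. With an estimated correlation, 1 of 100 splits, the real one, called as many as 6 lists, and the highest other called 0. The other splits mixed the groups here too, so this 0 does not measure what chance gives. List by list, a p as small as the real one came from 1 of 100 splits for DNA replication, nucleotide synthesis, germinal centre, MHC class I, the unfolded protein and ATF4 response, cholesterol synthesis, histones, and autophagy and lysosome, and from 2 for interferon and plasma cell lists. It came from 5 for MYC-activated genes and ribosome biogenesis, 10 for oxidative phosphorylation and B cell identity, 13 for cytosolic ribosomal proteins and 17 for mitosis. Each count includes the real split, and these are for the preset correlation. With an estimated correlation the counts were 2 for MYC-activated genes and 22 for B cell identity and for mitosis. They were 1 for ribosome biogenesis, oxidative phosphorylation and cytosolic ribosomal proteins. Splits that kept 4 arrays of a group together may be among those counted, so these counts are not plain chance rates. A list mean as far from 0 as the real one came from 1 of 100 splits for MYC-activated genes, ribosome biogenesis, oxidative phosphorylation, B cell identity and mitosis. For cytosolic ribosomal proteins it came from 18. Mixing the groups shrinks a real difference in means, so these counts have the same limit.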

How the results depend on the processing

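The filter on background was chosen after seeing the data. No called direction reversed under any alternative run. The STK38 fall kept its call in each one run for it, and leaving out each array in turn gave 1947 to 2817 changed probe sets. The count dropped to 1494 (650 higher) at an adjusted p of 0.01 and to 319 (100 higher, 219 lower) with a log2 fold change of at least 1, both by construction stricter, the second with 31.3% higher in place of 47.2%. Array weights raised the higher probe sets to 1619, against 1351 lower, and the cause was not tested. The balance of rises and falls is not firm: 47.2% were higher in the main analysis, 54.5% with array weights, 55.0% without STK38 shRNA replicate 4 and 50.5% after quantile normalization. With an estimated correlation 6 lists were called in place of 16, and the MYC-activated median of -0.17 was not called (adjusted p = 0.164, against 7.18e-07 to 0.00141 over its 19 other alternatives). A higher correlation between genes does not account for every weaker result. The histone list had an estimated correlation of -0.0019, under the preset 0.01, yet its camera p rose from 0.00584 to 0.0193. For the unfolded protein and ATF4 list (0.0086) the camera p rose from 3.45e-09 to 0.000320. What else weakened the calls was not tested. The MYC-repressed median of 0.082 was called by fry (adjusted p = 0.000433), which asks another question, and by no other alternative (0.178 to 0.461). Over the other lists 554 of 574 results kept their side of the threshold, 14 lost a call and 6 gained one; over named genes 1928 of 1960 did, with losses for MXI1 (9), CDK1 (8), CIITA (5) and UBE2C (5) and gains for MNT (5). The mitosis list lost its call under both stricter filters, and cytosolic ribosomal proteins lost theirs with each array centred on its median, without STK38 shRNA replicate 4 and by fry. The replicate block gave 2159 probe sets. The numbers are not taken to pair the arrays, since no label says that they mark a shared culture or day. Of 5 same-numbered pairs, 1 had deviations from the group means correlated above 0.1, and 1 array correlated best with its own number. STK38 shRNA replicate 4 shifts the mean of its group and so the deviations of all its arrays. These correlations therefore cannot decide whether the numbers pair the arrays. Scaling moved the median of all log2 fold changes from 0.018 to at most 0.025. The pseudocount for linear values was not run, since the values are on a log scale. Signal near background limits genes such as STK38L, WT1 and SLC2A3 to bounds.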

Other observations

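The tests of RPS12 and of DNA replication against mitosis were chosen after the results were seen; the further lists were fixed once the results of the first lists were known, with ATP6V0E1 and RPN2 left out because their values had been seen. Some of their members had been tested in the first lists, 4 of 15 synthetase, 3 of 19 translocon and all 24 remaining MYC-activated genes, and 0 of 13 V-ATPase genes. Genes of the vacuolar proton pump, which acidifies lysosomes, rose along with the lysosome list. Of 13 V-ATPase genes measured, 8 rose and 0 fell, with a median log2 fold change of 0.51. The camera p over these genes was 4.34e-05, and adjusted over the lists tested in this part it was 0.000108. With an estimated correlation the list was not called, adjusted p = 0.0702 over the same lists. ATP6V0D1, above background on 4 of the 5 control arrays, rose by 1.19 (SE 0.24), ATP6V1D by 1.13 (SE 0.094) and ATP6V0C by 1.03 (SE 0.13). Aminoacyl-tRNA synthetase genes, which charge transfer RNAs and include several ATF4 targets, fell: 10 of 15 fell and 0 rose, with a median of -0.46 (camera p = 1.66e-06, adjusted p = 8.30e-06, and adjusted p = 0.0200 with an estimated correlation). YARS1 fell by 0.68, EPRS1 by 0.67 and SARS1 by 0.62 on the log2 scale. AARS1, GARS1 and WARS1 belong to the ATF4 list as well, whose result was known, and a test without them was added afterwards. Of the remaining 12 genes 7 fell and 0 rose, with a median of -0.30. The camera p without the shared members was 0.000144, and adjusted it was 0.000241.

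The hypothesis that the fall of the unfolded protein and ATF4 list extends to the machinery that moves proteins into the endoplasmic reticulum was not borne out. Of 19 translocon and N-glycosylation genes, 5 fell and 2 rose, with a median of -0.064. The camera p over these genes was 0.329, and adjusted it was 0.329. SRP72 fell by 1.19 on the log2 scale and SRP14 rose by 0.72.

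MYC-activated genes that belong to neither the replication, the nucleotide nor the ribosome biogenesis list were not called as a group, in a test fixed after the result of the full list was known. Of 24 such genes, 7 fell and 3 rose, with a median of -0.11. The camera p over these genes was 0.113, and adjusted it was 0.141. HK2 fell by 1.25 on the log2 scale and TMEM97, which is also linked to sterol metabolism, rose by 0.80. The fall of the MYC-activated list may therefore rest on its shared members, in line with a p of 0.113 for the rest, though a p that misses the threshold does not show that the rest stayed level.

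RPS12 fell 4.93-fold while most ribosomal protein genes did not. A single faulty probe set is argued against, since the smaller fall of its 2 probe sets was -1.97. A general fall of ribosomal protein mRNA is argued against as well: the other 45 genes had a median of 0.11 and the lowest was at -0.55. Both RPS12 probe sets may share probes or bind the same related transcripts, which was not tested, and a direct effect of the hairpin on RPS12 mRNA could not be examined because no sequences were used here. No biological explanation was tested.

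DNA replication genes fell more than mitosis genes. The difference between the means of the lists was lower by 0.38 on the log2 scale with the STK38 shRNA (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 arrays allow), and by 0.37 without STK38 shRNA replicate 4. This test restates, on the same arrays, the list means of -0.61 and -0.24 that prompted it, so it is no independent support. One common fall of all proliferation genes is argued against by the 5 mitosis genes that rose, CDC20, PTTG1, CDK1, CKS2 and UBE2C, by 0.28 to 0.37 on the log2 scale. CDK1 and UBE2C lost their calls under some alternatives. A common fall of most of these genes, by unequal amounts, stays open, and a shift in cell cycle phase was not tested.

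Single genes of lists with no call also moved. JUN rose by a measured 1.29 on the log2 scale, but was above background on 1 control array, so the size is uncertain. JUND rose by 1.19, while MYB fell by 1.49. The chaperone gene HSP90AB1 fell by 1.17, the translation factor genes EIF3G and EIF2S2 by 1.38 and 1.18, PFKL by 0.84 and the proteasome gene PSMD2 by 0.93, and PSMB5 rose by 0.69. Among apoptosis regulators BCL2, above background on 4 of the 5 STK38 shRNA arrays, fell by 0.95, while CASP9 rose by 0.97 and BAK1 by 0.95.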
